A study of Homo sapiens with 9 samples.

How the data were processed

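RNA from 9 cultures or aliquots of the LNCaP line was sequenced, in 3 groups of 3 libraries: a control, a line with knockdown of UGT2B28, and a rescue in which UGT2B28 was overexpressed in the knockdown background. LNCaP is an established androgen-responsive human prostate cancer cell line. Per the labels, total RNA was used, the time point was 24 h, knockdown cells were selected with puromycin at 3 µg/mL and rescue cells with G418 at 1 mg/mL. The labels do not say whether the replicates were separate cultures, so the p-values measure only the spread between these libraries, which may be technical. Only 1 knockdown line was sequenced.

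The deposited values are raw counts of reads per gene, 1 table per library, with 60880 gene rows each. Per the submitters' processing notes, FastQC, cutadapt, HISAT2 and HTSeq were used with the hg19 build; their versions, the library kit and the strand setting of the counting are not given in the sources used here. Gene identifiers were matched to symbols without conversion of coordinates: 56414 matched the symbol table, 444 matched GENCODE v29 only, and 4022 had no symbol. The annotation at hand is of another build, so no coordinates are given, and gene models served only to tell which genes overlap or neighbour each other.

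Gene counts summed to 20300744 to 26459528 per library. They were 40.3% to 42.92% of the reads in each table; 48.83% to 50.71% lay in no gene, 2.26% to 2.67% were ambiguous and 5.26% to 7.62% did not align uniquely. These summary rows were left out of library sizes and tests. For a gene with no counts in a group, a fold was computed against a floor of 3 counts over the group's 3 libraries. Intervals and floors cover counting error only.

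Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10, which left 18389 genes. Libraries were scaled by TMM, a quasi-likelihood model with robust fit was fitted to all 9 libraries with 1 mean per group (6 residual degrees of freedom), and the 3 contrasts were tested with glmQLFTest. A gene was called when its Benjamini-Hochberg adjusted p was under 0.05. All adjusted p-values of single genes in the text come from this test. Log2 fold changes are given with a standard error (SE) worked back from the test. It is the absolute log2 fold change over the square root of the quasi-likelihood F. With few counts in a group it can fall below the SE of other tools. For UGT2B28 in rescue against knockdown it was 0.341, against 0.763 in DESeq2 and 0.681 in limma voom. Levels are given as mean CPM (edgeR's depth-normalized counts, with TMM-adjusted library sizes) ± SD over 3 libraries.

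A gene was counted as reversed when it was called in knockdown against control and in rescue against knockdown with opposite signs, and as kept when it was called with the same sign against control in knockdown and in rescue. Because these contrasts share libraries, 20 sets of unchanged groups were simulated to give the counts and covariances that sharing alone produces.

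Before the data were examined, 31 gene lists were fixed from general knowledge; 30 had at least 5 tested members and were tested in each contrast, 90 tests in all. The exception was the UGT2B family, with 4 tested members, which is described gene by gene. The test was camera in limma 3.58.1 on voom values with a preset correlation of 0.01, adjusted over the 90 tests. It was set beside camera with an estimated correlation, fry and cameraPR. The lists cover androgen response (induced and repressed), steroid metabolism, UDP-glucuronate supply, MAPK output, EGFR receptors and endocytic adaptors, cell cycle (G1/S and G2/M), cholesterol and fatty acid synthesis, ATF4 and unfolded protein responses, p53, interferon, NF-kB, NRF2, hypoxia, glycolysis, nuclear-encoded respiration, mitochondrial mRNA, ribosomal proteins, mesenchymal and epithelial genes, histones, structural noncoding RNA, and markers of luminal, basal, neuroendocrine and non-epithelial cells. 1 further list is not reported here.

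The genes named in the text also follow a rule fixed before the data were examined. It takes the UGT2B family; the 6 most raised and 6 most lowered genes per contrast with a symbol, an adjusted p under 0.05, no overlap between the libraries of the groups compared and a mean of at least 5 CPM in the higher group; up to 4 members of each described list with the smallest adjusted p; and the 5 reversed and 5 kept genes per direction with the largest smaller fold change. Names outside the rule are said to be chosen after their values were seen. The text names only part of the genes that the rule takes, and a Y-linked one is left out.

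The scripts were tested on simulated counts with known changes. For knockdown against control, 58.2% of genes changed 1.5-fold, 73.1% of those changed 2-fold and 93.9% of those changed 4-fold were recovered in the right direction. Of the unchanged genes 0.12% were called, among 17570 genes. The simulation changed only 67, 67 and 66 genes by these folds and 3 lists 1.4-fold, against 32.1% of genes called in the data. The cutoff of the adjusted p depends on that share, so these rates do not carry over to the data. The alternatives were DESeq2 1.42.0, limma voom, DESeq2-style and upper-quartile scaling, no or a stricter count filter (mean CPM of at least 1), the replicate number as a block, only the groups compared in the fit, a test against a fold change of 1.5, and leaving out each library in turn.

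Reads from near-identical gene copies cannot be assigned with certainty, which bears on histone, ribosomal protein, mitochondrial, ferritin and CTAG2 counts. Of the 150-nt stretches of annotated UGT2B28 transcripts, 100% occurred in no other gene, against 92.9% for UGT2B11 and 95.1% for both UGT2B15 and UGT2B17; at 60 nt the share for UGT2B28 was 75.0%. Genes inside an exon of a gene on the other strand carried reads at a median density of 1.48 times that of the outer gene, so counts of genes that overlap an opposite-strand gene are uncertain. Of the called genes, 206 in knockdown against control, 43 in rescue against knockdown and 247 in rescue against control had at least 50% of their exons under opposite-strand exons. Replicate libraries differed by more than sampling noise, so none was counted as a repeat of another. Control replicate 1 stood farthest apart: its chi-squared per degree of freedom was 22.01 and 18.38 against control replicates 2 and 3. These differed from each other by 5.05, and pairs within the other groups by 6.38 to 11.24. In knockdown against control the sign of UGT2B28, the direction of the ribosomal protein list and the call of nuclear-encoded respiratory genes changed without it.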

Results

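RNA sequencing compared control LNCaP prostate cancer cells, cells with knockdown of UGT2B28, and knockdown cells in which UGT2B28 was overexpressed again. UGT2B28 is a UDP-glucuronosyltransferase of a family that conjugates steroids, androgens among them, to glucuronic acid. Each group held 3 libraries, with 21483664 to 26004347 gene counts in control, 21753045 to 26145310 in knockdown and 20300744 to 26459528 in rescue. The first principal component held 46.9% of the variance and placed the 3 control libraries apart from the 6 others, and the second, with 12.8%, parted knockdown from rescue. The mean correlation of log2 CPM between libraries was 0.956 for control and knockdown, 0.976 for knockdown and rescue, and 0.9501 for control and rescue, against 0.9811 to 0.9825 within groups.

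The level of the targeted gene was examined first. UGT2B28 (ENSG00000135226.17_3) had 25, 4 and 10 counts in the control libraries and 17, 8 and 1 in the knockdown libraries, or 0.525 ± 0.38 and 0.344 ± 0.301 CPM (SD, n = 3). A difference between them was not detectable at this depth (log2 fold change −0.60, SE 0.62, edgeR adjusted p = 0.52), and its sign turned to 0.16 without control replicate 1. In the rescue libraries it had 1124, 1554 and 1857 counts, or 62.3 ± 7.23 CPM, above knockdown (log2 fold change 7.41, SE 0.34, adjusted p = 2.7e-08) and above control (log2 fold change 6.81). The size of both rested on few counts in the lower group: without knockdown replicate 1 the first was 8.264, and without control replicate 1 the second was 7.578. The counts thus neither show nor exclude a lower UGT2B28 level in the knockdown libraries, which are named by their label throughout. Rescue likewise names overexpression in the knockdown background, above the control level, and not a return to that level.

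Other members of the family differed between control and knockdown. UGT2B11 fell from 45.2 ± 4.71 CPM in control to 0.75 ± 0.19 in knockdown (log2 fold change −5.92, SE 0.22, adjusted p = 3.9e-17). UGT2B15 and UGT2B17, which inactivate androgens in prostate cells, fell from 94.0 ± 10.4 to 14.1 ± 2.06 CPM and from 127 ± 4.16 to 32.6 ± 4.34 CPM (log2 fold changes −2.74, SE 0.13, and −1.97, SE 0.11). In rescue, UGT2B15 and UGT2B17 were lower again than in knockdown, at 6.41 ± 1.27 and 16.7 ± 3.24 CPM (adjusted p = 2.5e-06 and 3.8e-06), and UGT2B11 was at 0.47 ± 0.327 CPM, with no call against knockdown (adjusted p = 0.40).

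**Figure D1:**
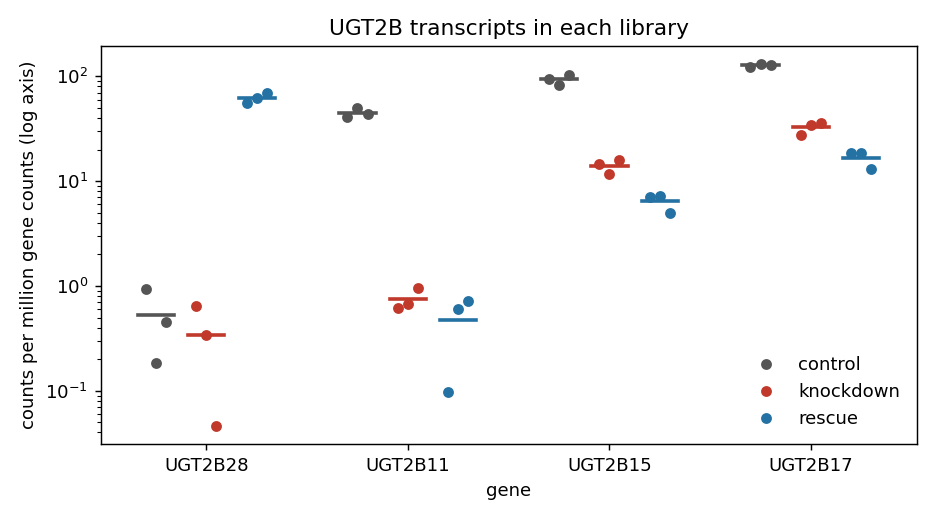
CPM of 4 UGT2B genes (log axis) in each of the 9 libraries, with points for libraries and lines for group means. UGT2B28 was at 0.046 to 0.936 CPM in control and knockdown libraries and at 55.1 to 69.6 CPM in rescue, while UGT2B11, UGT2B15 and UGT2B17 were highest in control.

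In knockdown against control, 20 of 29 androgen-induced genes were higher, all 13 mitochondrially encoded mRNAs were lower, and 7 of 15 mesenchymal genes were lower with 2 higher. As lists these passed with a preset correlation but not with an estimated one (adjusted p = 0.057, 0.13 and 0.079). KLK2, a kallikrein of the prostate, rose from 125 ± 12.4 to 1700 ± 82.9 CPM (log2 fold change 3.76, SE 0.09, n = 3), and the protease TMPRSS2 from 236 ± 1.22 to 815 ± 25.8 CPM. Of 18389 genes tested, 5899 (32.1%) were called, 3030 higher and 2869 lower, and 1445 of them differed at least 2-fold. Counts of list members called are to be read against that share. The most raised genes were TCEA3, FUCA2, EFS, EPHA6, SDK1 and SALL2, with log2 fold changes from 7.89 (SE 0.29) for TCEA3, a transcription elongation factor, to 4.89 (SE 0.38) for SALL2. FUCA2, a fucosidase, rose from 0.344 ± 0.096 to 41.5 ± 3.57 CPM. Among the most lowered, the desmosomal cadherin DSC3 went from 1392 counts to 2 over the 3 libraries, a ratio of 730 (95% counting interval 202 to 6040), and ECHDC1 from 419 counts to 3, a ratio of 147 (49.8 to 713). FRAS1, an extracellular matrix protein, fell by 7.44 on the log2 scale (SE 0.32), the integrin ITGA2B by 5.60 (SE 0.57) and DNAAF11 by 5.08 (SE 0.30). When a fold change above 1.5 was required by the test, 1141 genes were called.

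Androgen-induced genes rose as a list: of 29 tested members, 20 were higher, 1 was lower and 8 did not pass, with the same 20 and 1 adjusted over the list alone (camera adjusted p = 3.8e-12, adjusted p = 0.057 with an estimated correlation). FKBP5, a chaperone of steroid receptors, rose by a log2 fold change of 1.99 (SE 0.10) and CENPN by 1.63 (SE 0.08). KLK3, which encodes prostate-specific antigen and was chosen after its values were seen, rose by 1.39 (SE 0.086). Among 7 androgen-repressed genes, 4 were lower and 2 higher (adjusted p = 0.0078, adjusted p = 0.12 with an estimated correlation). The lower ones were the 3 UGT2B genes above and the opioid receptor OPRK1, which fell from 12.6 ± 0.971 to 0.536 ± 0.348 CPM.

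Lipid synthesis genes were higher in knockdown. Of 16 fatty acid synthesis genes 12 rose and 0 fell (adjusted p = 2.8e-11, adjusted p = 0.068 with an estimated correlation), among them the synthase FASN, from 1910 ± 322 to 4820 ± 340 CPM, and the desaturase FADS2, from 399 ± 28.7 to 993 ± 35.6 CPM. Of 23 cholesterol biosynthesis genes 14 rose and 1 fell (adjusted p = 3.1e-07, adjusted p = 0.11 with an estimated correlation), with log2 fold changes of 1.04 for MSMO1 and 0.91 for INSIG1, the sterol sensor. In glycolysis 11 of 17 rose and 0 fell (adjusted p = 2.6e-07, adjusted p = 0.11 with an estimated correlation), including the lactate transporter SLC16A3 at 1.84 (SE 0.20) and LDHA at 0.57 (SE 0.08). Of 21 hypoxia genes 13 rose and 4 fell (adjusted p = 4.2e-05, adjusted p = 0.13 with an estimated correlation), with PFKFB3 at 1.21 and P4HA1 at 0.97.

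Stress-response lists were also higher. ATF4 target genes rose in 13 of 25 cases and fell in 1 (adjusted p = 3.7e-05, adjusted p = 0.14 with an estimated correlation), led by DDIT4, an inhibitor of mTORC1 signalling, from 1070 ± 87.2 to 3270 ± 197 CPM. In the unfolded protein response 9 of 18 rose and 0 fell (adjusted p = 4e-05, adjusted p = 0.11 with an estimated correlation), with DNAJB9 at 1.09 and the chaperone HSPA5 at 0.66. Of 23 p53 targets 11 rose and 2 fell (adjusted p = 0.0034, adjusted p = 0.41 with an estimated correlation); GADD45A was higher by 0.92 and DDB2 lower, at −0.54. Adjusted over the list alone, the counts of higher and lower genes became 15 and 1 for cholesterol, 13 and 0 for glycolysis, 14 and 4 for hypoxia, 9 and 1 for the unfolded protein response and 11 and 5 for interferon, and were the same for fatty acid synthesis, ATF4 and p53. Interferon genes (8 higher and 4 lower of 28; adjusted p = 0.32) and NRF2 targets (4 higher and 3 lower of 15; adjusted p = 0.63) did not pass as lists.

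All 10 tested histone genes of the replication-dependent kind were higher in knockdown, with a median log2 fold change of 2.21 (adjusted p = 4.2e-14, adjusted p = 0.057 with an estimated correlation). H2BC21 rose from 41.6 ± 2.53 to 205 ± 27.3 CPM. All 13 mitochondrially encoded mRNAs were lower, with a median of −0.86 (adjusted p = 3.4e-14, adjusted p = 0.13 with an estimated correlation), and mitochondrial genes took 4.64% to 5.68% of gene counts in control, 2.56% to 2.89% in knockdown and 3.19% to 3.86% in rescue. MT-ATP6 fell from 2220 ± 266 to 1080 ± 53.4 CPM. Of 15 mesenchymal genes 7 fell and 2 rose, or 8 and 2 adjusted over the list alone (adjusted p = 0.00064, adjusted p = 0.079 with an estimated correlation): VIM, the intermediate filament vimentin, fell from 57.2 ± 5.05 to 7.53 ± 0.781 CPM and FN1, fibronectin, from 1210 ± 173 to 243 ± 13.8 CPM. The lists for these other cells were not called: basal epithelium (3 higher and 2 lower of 8; adjusted p = 0.82), fibroblast, endothelial and immune cells (2 and 2 of 5; adjusted p = 0.99) and neuroendocrine cells (0 and 1 of 6; adjusted p = 0.40).

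**Figure D2:**
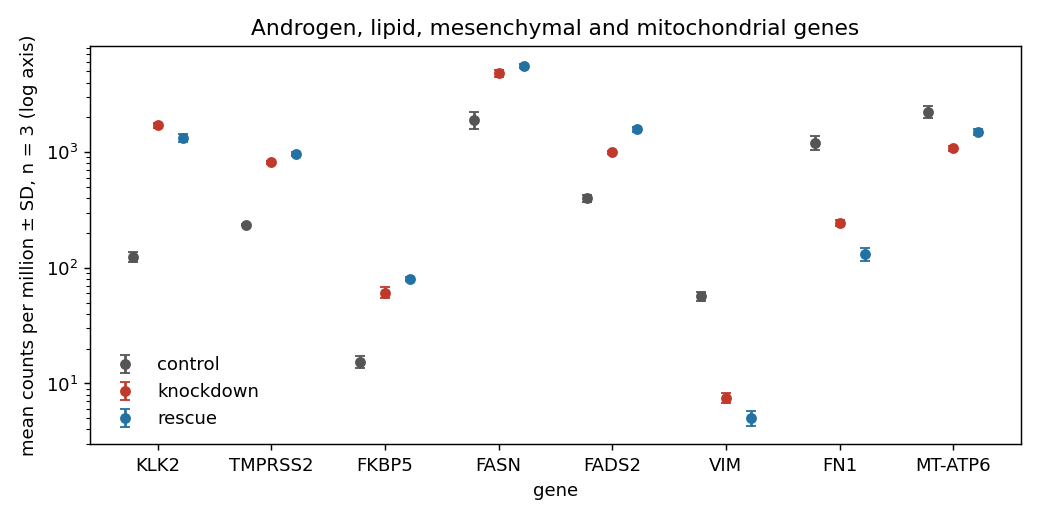
Mean CPM ± SD over 3 libraries (log axis) of 8 genes in control, knockdown and rescue. KLK2, TMPRSS2, FKBP5, FASN and FADS2 were higher in knockdown and rescue than in control, and VIM, FN1 and MT-ATP6 lower.

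Growth-factor receptor genes were examined next. Of 12 genes for EGFR-family receptors, ligands and endocytic adaptors, 1 was higher and 3 were lower in knockdown (adjusted p = 0.47). ERBB3 fell from 390 ± 28.8 to 259 ± 18.2 CPM and the clathrin adaptor HIP1R from 66.1 ± 5 to 44.0 ± 5.38 CPM. HBEGF, an EGFR ligand, was higher by 1.10 (SE 0.32, adjusted p = 0.008), a call lost without knockdown replicate 2 (adjusted p = 0.118). EGFR, chosen after its values were seen, had a log2 fold change of 0.16 (SE 0.095, adjusted p = 0.227). MAPK output genes (7 higher and 4 lower of 17; adjusted p = 0.17) went both ways: ETV1 rose by 1.37 (SE 0.10) and FOS by 1.30 (SE 0.09), and the phosphatase DUSP4 fell by 0.76 (SE 0.10).

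The rescue was compared with knockdown to see what changed when UGT2B28 was overexpressed in that background. Per the labels the selection antibiotic was puromycin for knockdown and G418 for rescue, so between these groups the antibiotic differed along with the construct. None is named for control, and whether control cells were selected is not stated. In rescue 11 of 13 mitochondrial mRNAs and 7 of 24 G2/M genes were higher, and 12 of 48 ribosomal protein and 3 of 9 NF-kB genes were lower. These list calls were lost with an estimated correlation (adjusted p = 0.14, 0.13, 0.41 and 0.069). Of 18389 genes, 1854 (10.1%) were called, 957 higher and 897 lower, and 284 differed at least 2-fold. After UGT2B28 itself, the most raised genes were PEG3, an imprinted zinc finger gene, from 43.9 ± 6.11 to 254 ± 15.9 CPM, PARVA at a log2 fold change of 2.08 (SE 0.25), the olfactory receptor OR51E1 at 1.97 (SE 0.20) and ALDH5A1 at 1.87 (SE 0.17). The most lowered were CTAG2, a cancer-testis antigen, from 7.71 ± 0.689 to 0.303 ± 0.199 CPM, PSMD5, TLL1, ACOX2, SDK1 and ZNF608, the last at −1.88 (SE 0.27). The count fell to 1196 without rescue replicate 1 and to 113 when a fold change above 1.5 was required by the test.

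Of the 13 mitochondrial mRNAs 11 rose from knockdown to rescue and 0 fell (camera adjusted p = 3.9e-12, adjusted p = 0.14 with an estimated correlation); MT-ATP6 reached 1490 ± 89.5 CPM, below its control level. In G2/M 7 of 24 genes rose and 0 fell, and 15 rose when adjusted over the list alone (adjusted p = 1.7e-07, adjusted p = 0.13 with an estimated correlation), with CCNA2, cyclin A2, at 0.42 (SE 0.08). Histone genes rose in 7 of 10 cases, or 8 adjusted over the list alone (adjusted p = 1.1e-08, adjusted p = 0.069 with an estimated correlation). Of 48 ribosomal protein genes 12 fell and 0 rose (adjusted p = 3.6e-13, adjusted p = 0.41 with an estimated correlation), RPL28 from 898 ± 125 to 617 ± 46.3 CPM. NF-kB genes fell in 3 of 9 cases (adjusted p = 0.00017, adjusted p = 0.069 with an estimated correlation), among them TNFAIP3 at −1.39 (SE 0.22), and NRF2 targets in 6 of 15 (adjusted p = 0.00018, adjusted p = 0.13 with an estimated correlation), among them HMOX1, heme oxygenase, at −0.52 (SE 0.08).

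Of the lists called in knockdown against control, only mitochondrial mRNAs were called in the opposite direction in rescue against knockdown with the preset correlation, and with an estimated one neither call held (adjusted p = 0.13 and 0.14). Androgen-induced genes had 10 members higher and 4 lower in rescue than in knockdown (adjusted p = 0.0048, adjusted p = 0.21 with an estimated correlation), with SLC45A3 higher by 0.96 (SE 0.08). KLK2 and CENPN had lower means in rescue, 1330 ± 99.3 against 1700 ± 82.9 CPM and 145 ± 13.5 against 195 ± 7.53 CPM. Fatty acid synthesis had 5 higher and 2 lower (adjusted p = 0.002, adjusted p = 0.20 with an estimated correlation), and FADS2 reached 1570 ± 76.8 CPM. The unfolded protein response had 4 higher and 0 lower (adjusted p = 0.00064, adjusted p = 0.13 with an estimated correlation) and p53 targets 4 higher and 0 lower (adjusted p = 0.003, adjusted p = 0.41 with an estimated correlation), with CDKN1A higher by 0.50. Androgen-repressed genes had 3 lower and 0 higher (adjusted p = 0.00064, adjusted p = 0.072 with an estimated correlation). Mesenchymal genes had 4 lower and 0 higher (adjusted p = 0.015, adjusted p = 0.14 with an estimated correlation), a call lost without knockdown replicate 3 (adjusted p = 0.0598); FN1 fell to 131 ± 16.8 CPM. Cholesterol (adjusted p = 0.17), ATF4 (0.99), hypoxia (0.23), glycolysis (0.47), interferon (0.13), MAPK (0.22) and EGFR-related genes (0.29) did not pass as lists. ATF4 targets had 2 higher and 3 lower, with DDIT4 at −0.56 (SE 0.09). MAPK genes had 0 higher and 3 lower, with ETV1 at −0.50 (SE 0.10). Adjusted over the list alone, the counts of higher and lower genes in rescue against knockdown were 14 and 5 for androgen-induced, 7 and 2 for fatty acid, 7 and 0 for unfolded protein response, 0 and 18 for ribosomal protein, 0 and 5 for NF-kB and 0 and 4 for androgen-repressed genes. Of 12 EGFR-related genes 3 were called higher in rescue than in knockdown, TGFA by 1.18, HIP1 by 0.40 and ERBB3 by 0.25. AP2M1 was called lower, at −0.25, and each of these calls was lost without some libraries. HIP1, an endocytic adaptor (SE 0.12, adjusted p = 0.027), was at 39.3 ± 6.96 CPM in control, 34.5 ± 4.75 in knockdown and 45.5 ± 2.92 in rescue. It lost the call without knockdown replicate 2 (adjusted p = 0.133), knockdown replicate 3 (0.116), rescue replicate 1 (0.124) or rescue replicate 2 (0.062).

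Genes were then sorted by whether the knockdown difference was reversed. Of the 1854 genes called in rescue against knockdown, 841 were not called in knockdown against control, so the sorting leaves them out. Of the 5899 genes called in knockdown against control, 552 (9.4%) were called in the opposite direction in rescue against knockdown, 461 (7.8%) moved further the same way, and 4886 (82.8%) were not called in rescue against knockdown. Among the reversed genes, CTAG2 went from 0.324 ± 0.271 CPM in control to 7.71 ± 0.689 in knockdown and 0.303 ± 0.199 in rescue, and DHX58, an RNA sensor, from 2.12 ± 0.353 to 9.08 ± 1.23 and 2.47 ± 0.18. In the other direction, H2AJ, a histone variant, went from 62.0 ± 3.98 to 23.1 ± 1.99 and 74.6 ± 2.79 CPM, and PLP2 from 22.2 ± 0.449 to 4.47 ± 0.341 and 13.7 ± 2.32. PSMD5, ACOX2 and SDK1, higher in knockdown, and TUSC1 and RTL5, lower in knockdown, returned part of the way. Of the 552, 330 were no longer called against control. Independent lists of these sizes would share 297.1 genes in opposite directions and 297.6 in the same direction, so the observed 552 and 461 both lay above that value. Unchanged groups that share the knockdown libraries gave 0 to 1 reversed genes, since with no change hardly any gene is called. The covariance of the fold changes was −0.068, against −0.046 from sharing alone. Both contrasts hold the same knockdown libraries with opposite signs, which independent lists leave out. Part of the count of reversed genes may therefore come from the shared libraries. The count fell to 356 without rescue replicate 3.

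Rescue against control gave 6946 calls (37.8% of tested genes), 3492 higher and 3454 lower, and 1723 of at least 2-fold. Of the knockdown calls, 4469 (75.8%) were called in the same direction here, against 1114.3 for independent lists. These overlap the reversed genes: 186 of the 4469 had moved back toward control in rescue against knockdown, and 3822 (64.8% of the knockdown calls) were not called in rescue against knockdown. Simulated unchanged groups gave 0, since with no change hardly any gene is called. The covariance of the fold changes was 0.65, against 0.047 from sharing alone. The 3 control libraries were not split between the contrasts, since 1 part would hold fewer than 2, so part of the excess of calls may come from the shared controls. The chemokine CXCL12 had 0 counts in control and was at least 55-fold higher in knockdown and at least 193-fold higher in rescue, with the floor of 3 counts over the group (lower 95% counting limits 44.2 and 156). PHGR1, with 1 control count, had ratios of 238 (42.4 to 9450) and 405 (72.3 to 16000). TCEA3 (log2 fold change 8.19), EFS (7.24) and FUCA2 (6.01) also stayed higher, and DSC3 (−7.09), UGT2B11 (−6.49), FRAS1 (−6.26), ITGA2B (−5.27) and ECHDC1 (−5.16) lower. FUCA2 was at 22.3 ± 2.29 CPM in rescue, below its 41.5 ± 3.57 CPM in knockdown. SPATA18, a mitochondrial quality control gene, was at 9.13 ± 2.1 CPM in rescue and 0.073 ± 0.0959 in control, and OPRK1 at 0.186 ± 0.103 against 12.6 ± 0.971.

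**Figure D3:**
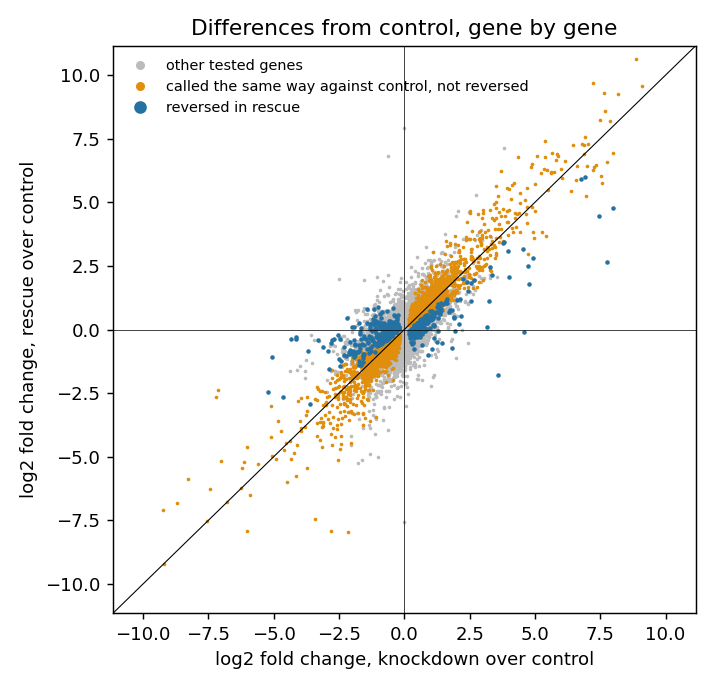
Log2 fold change against control of the 18389 tested genes, in knockdown (x axis) and in rescue (y axis), with the line of equal change. Blue points are the 552 reversed genes, between that line and the x axis or beyond the axis, and orange points are genes called the same way in both and not reversed, so 186 of the 4469 called the same way are drawn in blue.

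Rescue was also compared with control by list. Androgen-induced genes had 22 higher and 2 lower of 29 (camera adjusted p = 2.2e-13, adjusted p = 0.057 with an estimated correlation), with KLK2 at 3.41 (SE 0.09). Fatty acid synthesis had 12 higher and 0 lower (2.3e-10, adjusted p = 0.069 with an estimated correlation), cholesterol 14 and 2 (9.2e-07, adjusted p = 0.11 with an estimated correlation), the unfolded protein response 14 and 1 (2.9e-07, adjusted p = 0.069 with an estimated correlation) and ATF4 targets 15 and 0 (6.9e-06, adjusted p = 0.13 with an estimated correlation). Histones had 10 higher and 0 lower (2.8e-14, adjusted p = 0.057 with an estimated correlation), p53 targets 14 and 2 (3.9e-05, adjusted p = 0.25 with an estimated correlation) and G2/M 12 and 0 (0.00015, adjusted p = 0.21 with an estimated correlation). Hypoxia had 11 higher and 3 lower (0.00011, adjusted p = 0.14 with an estimated correlation) and glycolysis 12 and 2 (0.00015, adjusted p = 0.17 with an estimated correlation). Lower lists were mesenchymal genes, 9 lower and 1 higher (0.00018, adjusted p = 0.069 with an estimated correlation), mitochondrial mRNAs, 9 and 0 (2.2e-05, adjusted p = 0.35 with an estimated correlation), and androgen-repressed genes, 4 and 2 (0.0034, adjusted p = 0.11 with an estimated correlation). Luminal prostate genes had 7 higher and 3 lower of 14 (0.0063, adjusted p = 0.25 with an estimated correlation). Nuclear-encoded respiratory genes had 5 higher and 0 lower of 29 (0.016, adjusted p = 0.67 with an estimated correlation), a call lost without control replicate 1 (0.307) and without rescue replicate 2 (0.0644). Adjusted over the list alone, the androgen-induced list had 23 higher and 3 lower, fatty acid synthesis 12 and 1, cholesterol 15 and 2, the unfolded protein response 15 and 2, ATF4 targets 16 and 0, p53 targets 15 and 2, hypoxia 11 and 4, mesenchymal genes 2 and 9 and mitochondrial mRNAs 0 and 10. The counts of the other lists in this paragraph were the same. Over the 3 contrasts 42 of 90 list tests passed with the preset correlation and 0 with an estimated one, where the lowest adjusted p was 0.057 and 28 had an unadjusted p under 0.05. The fry test passed 53.

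**Figure D4:**
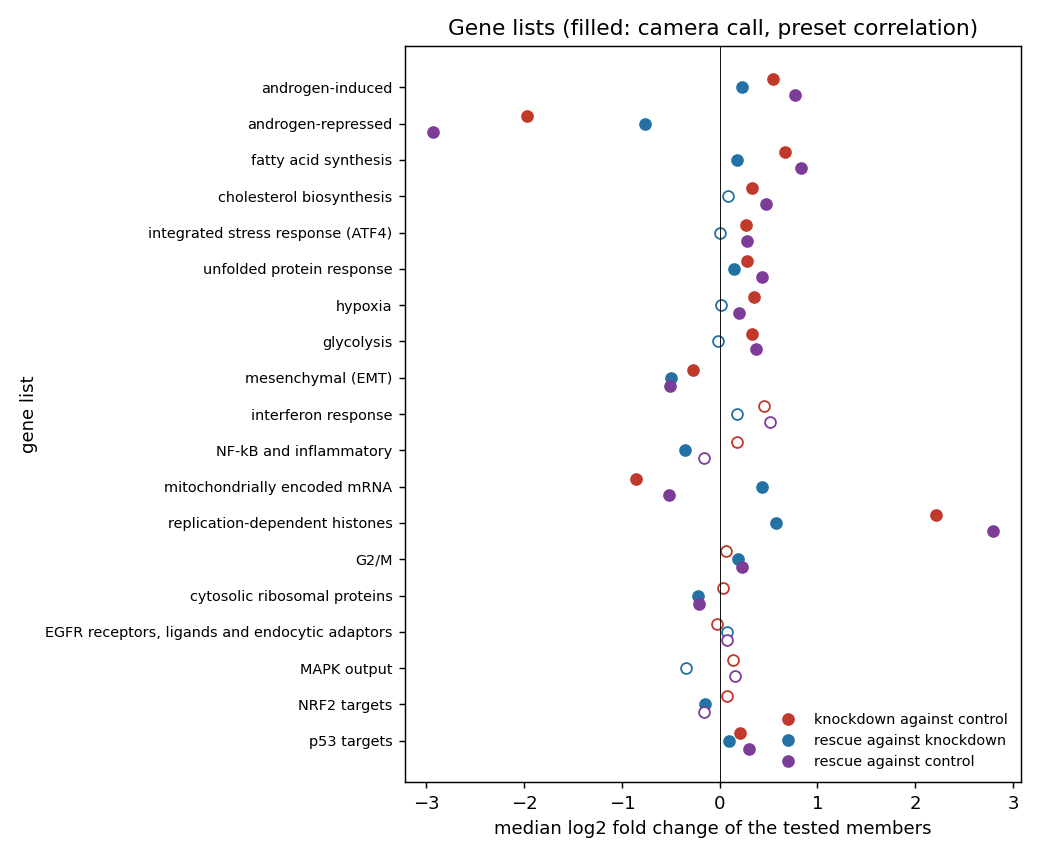
Median log2 fold change of the tested members of 19 gene lists in the 3 contrasts; filled circles passed camera with the preset correlation. Histones (2.21 and 2.79) and androgen-repressed genes (−1.97 and −2.93) lay farthest from 0 against control.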

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

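The alternatives were chosen before the data were examined; the counts over other splits of the libraries were given their bounds only after they had been seen. DESeq2, limma voom, both other scalings, both other filters, the fit of only the groups compared and the fit with a replicate block kept each count of called genes within 1.5 times its value. A test against a fold change of 1.5 left 1141 genes in knockdown against control, 113 in rescue against knockdown, 1482 in rescue against control, 40 reversed and 818 kept; the stricter null hypothesis is the cause. Camera with an estimated correlation passed 0 of 90 list tests, against 42. Leaving out 1 library gave 1196 to 2364 calls for rescue against knockdown (lowest without rescue replicate 1) and 356 to 637 reversed genes (lowest without rescue replicate 3); these fits have fewer libraries. UGT2B28 in knockdown against control ranged from −1.455 to 0.164 and was never called. The list of cytosolic ribosomal proteins in knockdown against control (adjusted p = 0.293) ranged from 0.00264 to 0.982 when libraries were left out, and passed as lower without control replicate 1 (0.00349) but as higher, the direction with all libraries, without control replicate 2 (0.00264), control replicate 3 (0.0084) or knockdown replicate 1 (0.0197); the cause was not tested. In rescue against control that list (0 higher and 14 lower of 48 and adjusted p = 0.00084 and adjusted p = 0.73 with an estimated correlation) lost its call without control replicate 2 (0.0975) and without control replicate 3 (0.0547). Of 278 results for named genes, 0 reversed; 121 lost their call in the 1.5-fold test, and 100 calls were lost over the fits without 1 library. The numbers gave little sign of pairing: deviations of same-numbered libraries correlated at −0.037 to 0.077. In both other groups at once, 0 libraries correlated best with their own number. The replicate block gave 6348, 2319 and 7363 calls, 715 reversed and 4847 kept genes, and 47 lists. Each of these counts was higher than without the block, so some variation shared by number is not excluded. For each contrast the 10 splits of its 6 libraries are too few for a share under 0.05; the real split, 1 of 10, called 5899, 1854 and 6946 genes, and the highest of the others 0. Over 100 splits of all 9 libraries the real one alone (1 of 100) gave as many reversed genes (552, highest other 91), kept genes (4469, highest other 3771, with the 3 controls together) and lists (42, highest other 41). The list count hardly sets the real split apart. Splits that mix the groups widen the spread within them, so a first rank for the real split was likely in advance. This count therefore does not exclude chance, and it does not bear on differences between cultures. A first draw of 100 counted the same 3 sets under other group names separately. It was replaced after its counts were seen: 2 of 100 then reached the real value for reversed genes (highest other 1163) and for lists (42), the second being the real sets with their names exchanged. Depth limits UGT2B28 in control and knockdown, at 1 to 25 counts per library.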

Other observations

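Nuclear-encoded respiratory genes were higher in knockdown than in control in 5 of 29 cases and lower in 0. The share higher was near that of all tested genes, 3030 of 18389. The list passed (camera adjusted p = 0.003 and adjusted p = 0.60 with an estimated correlation), a call lost without control replicate 1 (adjusted p = 0.178). The 13 mitochondrially encoded partners were lower. In rescue against knockdown the nuclear-encoded genes did not pass (camera adjusted p = 0.81). Luminal prostate genes were higher in rescue than in knockdown in 4 of 14 cases, or 7 adjusted over the list alone (adjusted p = 0.00097 and adjusted p = 0.20 with an estimated correlation). Several lists lay near the threshold in knockdown against control and crossed it when some libraries were left out. Luminal genes (6 higher and 3 lower, adjusted p = 0.053) passed without control replicate 1 (0.00866), knockdown replicate 1 (0.0494), knockdown replicate 2 (0.0242), rescue replicate 1 (0.0464) or rescue replicate 3 (0.0474). Epithelial junction and keratin genes (8 higher and 5 lower of 20, adjusted p = 0.053) passed without control replicate 1 (0.0235), control replicate 2 (0.0441), knockdown replicate 1 (0.0494), knockdown replicate 3 (0.024), rescue replicate 1 (0.0478) or rescue replicate 3 (0.0474). Genes of UDP-glucuronate supply (3 and 0 of 9, adjusted p = 0.054) passed without control replicate 2 (0.034), knockdown replicate 1 (0.0369), knockdown replicate 3 (0.0421), rescue replicate 1 (0.049) or rescue replicate 3 (0.0474). The NF-kB list (4 and 0 of 9, adjusted p = 0.067) passed without control replicate 1 (0.0439) or knockdown replicate 3 (0.0473), and G1/S genes (7 and 2 of 25, adjusted p = 0.075) without knockdown replicate 2 (0.0388). Adjusted over the list alone, the counts were 6 and 4 for luminal, 4 and 0 for UDP-glucuronate, 8 and 2 for G1/S and 6 and 1 for steroid metabolism genes. The lists for steroid metabolism (5 and 1 of 13, adjusted p = 0.47), structural noncoding RNA (1 and 1 of 5, 0.44) and G2/M (4 and 1 of 24, 0.40) did not pass in that contrast. In rescue against control G1/S genes (12 and 2 of 25, adjusted p = 0.053), interferon genes (12 and 3 of 28, 0.065) and UDP-glucuronate supply (5 and 1 of 9, 0.075) also lay near the threshold. Each passed without some libraries, at lowest 0.0109 and 0.0359 without rescue replicates 3 and 2, and 0.0459 without control replicate 2.

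In the next 3 paragraphs, the tests of shared reads, exchanged labels, androgen-repressed genes, shared controls, too little UGT2B28 RNA, genomic DNA and an unstranded library were chosen after the result was seen, and the bounds for copy number were written before its test was computed. UGT2B28 was at 1 to 25 counts per library in control and knockdown, while UGT2B11, UGT2B15 and UGT2B17 fell. Reads of UGT2B28 counted for UGT2B11 are argued against by the rescue libraries, where UGT2B11 counts were 0.79% of UGT2B28 counts; the construct's extent is not known, so this covers the part it carries. Exchanged control and knockdown labels are argued against by the lowest correlation of a knockdown with a rescue library, 0.9742, above the highest of a control with a rescue library, 0.953. A general fall of androgen-repressed genes may be part of it but cannot be told apart, since 1 of the 4 measured members outside the family was lower and 2 were higher. An effect of the knockdown reagent on UGT2B11 or its relatives stays open and was not tested, as the reagent's sequence was not used here.

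Of 5899 genes called in knockdown against control, 4469 were called the same way in rescue against control, 186 of which had also moved back in part, and 3822 were not called in rescue against knockdown. Shared control libraries alone gave a covariance of fold changes of at most 0.053 in simulation, against 0.65 observed. The UGT2B28 RNA level in rescue was 112-fold above control, with a log2 fold change of 7.578 in place of 6.81 without control replicate 1. This argues against too little UGT2B28 RNA only in the sense of a level below control. Control was near the floor, at 0.525 CPM, so almost any expressed construct would have passed, and protein and activity were not measured. Copy-number differences between the lines were weighed by the order of genes along chromosomes: 0% of windows of 200 genes had a median beyond 0.3 in knockdown against control (−0.203 to 0.299), under the 2% set beforehand as counting against it. Of both conditions set for it as the cause, a correlation of neighbouring genes of at least 0.2 was met, at 0.208 (0.027 at 5 places apart), and 10% of windows beyond 0.3 was not. In rescue against control 3.09% of windows lay beyond 0.3, with medians from −0.364 to 0.457, and neighbours correlated at 0.222. Regional shifts therefore stay open as a part of the differences. A stable difference between the control line and the knockdown line from which the rescue was made, by selection or by drift, may account for the pattern and was not tested, since 1 line stood for each group. An effect of the selection antibiotics, puromycin for knockdown and G418 for rescue by the labels, stays open and was not tested either.

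In each library 48.83% to 50.71% of reads lay in no gene. Genomic DNA alone is argued against, since genes inside an opposite-strand exon had reads more often than free genes of the same classes, by 47.6 percentage points. An unstranded library counted by strand may account for it: the 290 inner genes carried reads at a median of 1.48 times the density of the outer gene, where correct strand assignment would leave few. Reads from introns stay open as a further part, and no biological explanation was tested.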
